A study of Mus musculus with 42 samples.

How the data were processed

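The series holds 42 libraries from mouse embryonic stem cells (ESCs), 32 of polyA-selected RNA and 10 of small RNA, in 4 tables of values. KH2-ISY1 is an ESC line in which doxycycline (Dox) switches on a Flag-tagged copy of ISY1, a splicing factor. The polyA libraries comprise 7 of a course of embryoid body (EB) formation without Dox that starts in serum/LIF, 1 of serum/LIF cells with Dox, 10 of a course from 2i/LIF into epiblast-like cells (EpiLCs) without Dox, 4 of EpiLCs with Dox, 6 of a DGCR8 knockout (KO) line taken through the same medium, and 4 of cells returned from EpiLC to 2i/LIF (cESCs), 2 from EpiLCs without Dox and 2 from EpiLCs with Dox. The small RNA libraries comprise 3 of the EB course, 1 of serum/LIF cells with Dox, 3 of the EpiLC course, and 3 of V6.5 ESCs treated with short interfering RNA (siRNA): 1 with a control (siCTRL) and 2 with siRNA against Isy1. Each condition and time has 1 library, and the labels give no library batch. The labels do not say whether the 2 libraries with siRNA against Isy1 are replicates or hold different siRNAs.

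The labels name Trizol for RNA extraction, 3 ug of total RNA per polyA library, a TruSeq stranded kit for polyA RNA and a New England Biolabs kit for small RNA. The submitters' notes name the aligner Bowtie without a version, and the genome builds GRCm38 and mm9 without their roles. The gene counter, the annotation, the microRNA reference set and the normalisation are not stated. The deposited values of all 4 tables are of the unit signal, a scaled measure whose scale was worked out from the numbers. In the polyA tables low values were whole multiples of 1 step per library, so the authors divided gene read counts by 1 size factor per library. Whole reads were recovered for 24 of the 32 polyA libraries, in which the worst library had 93.9% of values within 0.1 reads of a whole number and the rounding allowed an error of up to 0.107 reads. The other libraries were not treated as recovered, among them the knockout library at 6 h, although it came slightly closer (94.7% and 0.105 reads). The EpiLC table has 16346 lines, of which 1 has no gene name and was left out, and the EB table has 16753 genes. Spreadsheet-like dates stand in place of 20 gene names in the EpiLC table and of 22 in the EB table, and these genes were kept but not named. In the microRNA tables, with 256 microRNAs in KH2 cells and 264 in V6.5 cells, the deposited values are signal on an unstated scale with unequal library totals, so each comparison is given with and without a further scaling.

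Total reads per polyA library ranged from 5.80 to 56.02 M reads. A single read corresponded to 0.0952 to 0.935 normalised units, which sets the precision of low values. A gene listed at 0 had no read counted in that library, but its expected count may be up to 3 reads (the floor used for an absent count, per library). Such limits cover counting error only.

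Values were analysed as log2(value + 1). Genes with a mean of at least 1 over the libraries of a fit were tested with limma 3.58.1 (empirical Bayes with an intensity trend) in R 4.3.3, and two-sided p values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The effect of Dox was fitted over 4 pairs of libraries (24, 48, 72 and 96 h) and that of the knockout over 6 pairs (0, 6, 24, 48, 72 and 96 h), each with hour as a block, so that the spread of the difference over hours stands in for replicate spread. These fits have 3 and 5 residual degrees of freedom. The courses were fitted as a natural spline of the square root of time with 3 degrees of freedom for EpiLC and 2 for EB, leaving 6 and 4 residual degrees of freedom, and direction is the fitted value at the last time minus the first. A gene was called transient when its fitted extreme lay between 12 and 36 h and at least 1.5-fold beyond both ends. The change of a paired difference with hour was tested with the same tool.

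A total of 24 gene lists were fixed before the data were examined. They are naive pluripotency, core pluripotency, formative epiblast, primitive streak, primitive and visceral endoderm, neuroectoderm, mesoderm and heart, blood and endothelium, trophoblast, germline, two-cell-like, feeder fibroblast, miR-290/302 targets, miR-17-92 targets, let-7 targets, microRNA machinery, microRNA host transcripts, Prp19 complex, MEK/ERK targets, Wnt targets, p53 targets, DNA methylation, interferon response and glycolysis. Some genes stand in more than 1 list, among them Tet2, Dnmt3a, Dnmt3b, Lef1, T, Hand1, Lefty1, Lefty2, Cdkn1a, Tgfbr2, Lin28a and Isy1. A list with at least 3 measured members was tested with camera, which compares the list with all other genes, at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the 23 lists that could be tested. On the courses camera tested a linear trend in the square root of time, not the spline or the fitted change between the ends. The 11 microRNA host transcripts are in neither table, so that list has no result. A further 14 microRNA lists (clusters and families) were fixed as well. Names in V6.5 cells can end in a locus number, which was dropped in matching, so several loci can stand for 1 list member.

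Where 1 library is compared with 1, no test was made. A gene was counted as changed with at least a 2-fold difference and a value of at least 5 in the higher library. A microRNA was counted with at least a 2-fold difference and a value of at least 100 in the higher library. For scaled counts this floor was applied to the scaled values, so the set of microRNAs counted also differs with scaling. With siRNA against Isy1, a microRNA was counted when it changed at least 2-fold in the same direction in both libraries. Its value had to reach 100 in at least 1 of these libraries or the control. A score per library, the mean log2 value of the naive pluripotency list minus that of the formative epiblast list, was compared within hours by an exact two-sided permutation test (sign flips). Each library with Dox, of the knockout or of cESCs was also placed on the EpiLC course by its highest Pearson correlation with a library without Dox, across the 1000 most variable genes.

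Genes to be named were set by a rule fixed before the data were examined: Isy1 and Dgcr8 first; the called list members of largest change, up to 4 per list; the 6 largest changes in each direction of each fit among genes that changed the same way at every hour and had a mean of at least 5 in the higher arm; for the EpiLC course also the 6 rising and 3 falling transient genes of largest excess; the 4 largest changes in each direction where 1 library is compared with 1; and the 5 largest for microRNAs, with the members of 4 microRNA families nameable throughout. Other genes that appear were chosen after their values were seen, and the text says so. Of the genes the rule names, 4 are not reported here.

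The alternatives tried were another scaling (median ratio, and a form of TMM on the deposited values), no filter, other pseudocounts and floors, no intensity trend, no hour block, other spline settings, and each pair or library left out in turn. A quasi-likelihood test of edgeR 4.0.16 on recovered reads was added after the data were seen. On simulated data the Dox fit recovered 84% of genes changed 2-fold and the knockout fit 100.0%, while the EpiLC course recovered 20% at 2-fold and 87% at 4-fold, with 13% of its calls false, and the EB course 26% and 91%. Simulated counts varied around 1 mean per gene with a dispersion of 0.03, and changed genes had a mean of at least 10. In the paired fits the simulated change was the same at every hour. Real differences varied with hour, so these shares may overstate what the real fits recover. In the list test on simulated data the shifted list was found in both paired fits, and in the Dox fit 1 unchanged list was called too. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No library was left out.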

Results

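Gene expression was measured by polyA RNA sequencing in 32 libraries and microRNA levels by small RNA sequencing in 10, all from mouse embryonic stem cells. In the KH2-ISY1 line doxycycline (Dox) induces Flag-tagged ISY1, a splicing factor of the Prp19 complex, and DGCR8 is the RNA-binding partner of the nuclease that cuts primary microRNA transcripts. The EpiLC table covers 10 libraries without Dox (0, 6, 12, 18, 24, 30, 36, 48, 72 and 96 h after 2i/LIF cells entered epiblast-like cell medium), 4 with Dox (24, 48, 72 and 96 h), and 6 of a DGCR8 knockout line (0, 6, 24, 48, 72 and 96 h). It also covers 4 of cells returned to 2i/LIF (cESCs) from 24 h or 48 h EpiLCs, with or without Dox. The EB table covers 7 libraries without Dox (day 0 in serum/LIF, then days 1, 2, 4, 8, 10 and 13) and 1 of serum/LIF cells with Dox. There is 1 library per condition and time, so no value has a replicate error of its own.

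Total reads in the EpiLC libraries without Dox were 6.35, 9.15, 9.29, 9.42, 6.22, 9.71, 9.54, 6.17, 11.42 and 13.15 M in order of hour. They were 6.16, 6.39, 15.08 and 11.95 M with Dox and 17.84, 11.68, 12.91, 11.77, 33.47 and 38.84 M in the knockout. The cESC libraries held 6.25 and 5.80 M reads from EpiLCs without Dox at 24 and 48 h, and 6.31 and 6.10 M from EpiLCs with Dox. The EB libraries held 23.84, 56.02, 23.71, 8.82, 9.51, 9.30 and 9.31 M reads in order of day, and the serum/LIF library with Dox 23.53 M. For small RNA the files give scaled values and no read depth, and the summed values per library ranged from 48534 to 393089.

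Isy1 transcript stood at 3038 normalised reads at 24 h of Dox against 423 without it, and the gap narrowed with time to 912 against 397 at 48 h, 1109 against 558 at 72 h and 708 against 418 at 96 h. The mean log2 difference over the 4 pairs was 1.45 ± 0.31 (SE), with a limma adjusted p of 0.0542, so Isy1 itself missed the threshold in that fit. It passed without the 24 h pair. In serum/LIF cells Isy1 was 5096 with Dox and 328 without. Along the EpiLC course without Dox, Isy1 rose by 0.79 on the log2 scale (adjusted p = 0.0255), a call that ended without the 0 h library. Dgcr8 transcript fell by 1.48 ± 0.20 (SE, 6 pairs) in the knockout, where it lay between 36.8 and 44.5 in every library (adjusted p = 0.000703), while Isy1 did not pass there (log2 −0.03, adjusted p = 0.816). Dgcr8 did not pass with Dox (log2 0.32, adjusted p = 0.388).

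**Figure D1:**
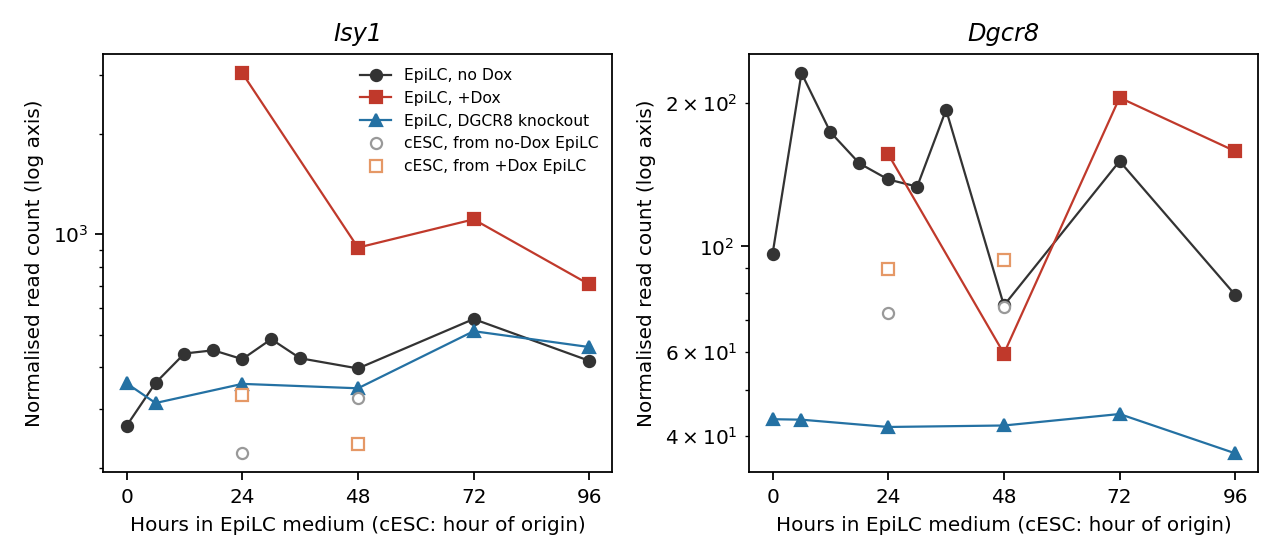
Normalised read counts of Isy1 (left) and Dgcr8 (right) on log axes against hours in EpiLC medium, or the hour of origin for cESCs, with 1 library per point. Isy1 lies at 3038 at 24 h of Dox and between 708 and 1109 later, against 267 to 558 without Dox, and Dgcr8 lies between 36.8 and 44.5 in the 6 knockout libraries.

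The EpiLC course without Dox asks which genes change as naive cells enter the formative state. Genes of the naive pluripotency list fell, among them Tcl1 (an Akt co-activator, −7.92 on the log2 scale between the fitted ends), Nr5a2 (a nuclear receptor, −7.18), Klf4 (−6.88) and Tbx3 (−6.56; adjusted p = 5.92e-05, 1.47e-05, 0.000156 and 2.97e-05). Members of the formative epiblast list rose, such as Fgf5, a growth factor of the postimplantation epiblast, by 8.56, the transcription factors Sox3 by 8.18 and Pou3f1 by 5.76, and the Wnt antagonist Sfrp2 by 6.33. In observed values, Klf4 went from 2519 at 0 h to 12.3 at 96 h and Pou3f1 from 14.8 to 754, while Fgf5 was listed at 0 at 0 h and stood at 449 at 96 h. Of the core pluripotency list, Lin28a rose by 4.35, Utf1 rose by 3.25 and Sox2 fell by 3.83, while Pou5f1, which encodes Oct4, fell by 0.59 (adjusted p = 7.91e-06, 4.23e-06, 5.85e-06 and 0.0018). In all 8125 of 16206 tested genes changed (4114 higher and 4011 lower at the end), 4290 of them at least 2-fold.

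Of the 21 naive genes 20 ended lower and 1, Gbx2 (named after its value was seen), ended higher by 0.30, and adjusted over the list alone the counts were the same numbers. The list test gave adjusted p = 2.52e-11 and adjusted p = 0.0139 with an estimated correlation. Of the 15 formative genes 12 ended higher and 2 lower, also adjusted over the list alone (adjusted p = 1.1e-06, and adjusted p = 0.298 with an estimated correlation). Of the 7 two-cell-like genes, named for transcripts of the early embryo, 6 rose and 0 fell, also adjusted over the list alone, with Zscan4c up by 5.12 and Zscan4b by 4.17 (adjusted p = 0.000236, and adjusted p = 0.336 with an estimated correlation). No other list passed this test of a linear trend on this course, which can miss a list that changes early and then levels off. The counts that follow therefore describe members and not groups. Of 11 MEK/ERK targets 8 rose and 1 fell, with Dusp6, a phosphatase that acts on ERK, up by 5.43 and Dusp4 by 3.93. The Dusp6 call ended without the 0 h library, and the targets Myc (6.06) and Spry4 (5.40) changed sign to −0.36 and −2.95 without it. DNA methylation genes split, with the methyltransferases Dnmt3a and Dnmt3b up by 4.33 and 3.92 and the demethylating enzyme Tet2 down (log2 −3.72), 4 up and 3 down of 8. Genes of the primitive and visceral endoderm list also split 4 to 4 of 10, Lama1 (a laminin) falling by 5.22 while Col4a1 (a collagen) rose by 4.10.

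Members called higher and lower in the other lists on this course were 5 and 3 of 9 for core pluripotency, 5 and 3 of 11 for primitive streak, 5 and 2 of 8 for neuroectoderm. They were 3 and 5 of 9 for mesoderm and heart, 0 and 2 of 5 for blood and endothelium, 3 and 4 of 9 for trophoblast, 4 and 2 of 9 for germline, and 4 and 0 of 5 for feeder fibroblast. For the microRNA-related lists they were 3 and 3 of 13 for miR-290 and miR-302 targets, 4 and 2 of 7 for miR-17-92 targets, 6 and 2 of 11 for let-7 targets, and 7 and 0 of 14 for the microRNA machinery. They were 2 and 2 of 10 for the Prp19 complex, 2 and 3 of 7 for Wnt targets, 2 and 3 of 10 for p53 targets, 5 and 0 of 6 for the interferon response, and 7 and 2 of 12 for glycolysis. Adjusted over the list alone, the counts differed in these lists for primitive streak (5 and 4), blood and endothelium (0 and 3), miR-17-92 targets (4 and 3), microRNA machinery (8 and 0) and p53 targets (3 and 5). The signs of mean, median and test differed in 6 lists, none of them below the threshold.

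Among the largest rises of the course were Fndc3c1 (9.58), Trim67 (9.54) and Thbs1 (thrombospondin, 9.52), and among the largest falls Jam2 (a junction protein, −8.57) and Aqp3 (a water channel, −8.30), on the log2 scale. Transient genes with a peak numbered 1099 and those with a trough 1164. The 12, 18, 30 and 36 h libraries held 9.29 to 9.71 M reads, 24 h held 6.22 M, and the ends, 0 h and 96 h, held 6.35 and 13.15 M. A transient shape is thus largely confounded with library depth, and whether these calls depend on it was not tested. Pla2g7, a secreted phospholipase, went from 7.80 at 0 h to 1209 at 6 h and 3.00 at 96 h, with a fitted excess of 5.77 over the nearer end. Dnmt3l, a cofactor of the methyltransferases, went from 55.7 at 0 h to 2092 at 36 h and 64.7 at 96 h (excess 5.09), and Bmp4, a signalling ligand, from 9.60 at 0 h to 341 at 12 h and 8.50 at 96 h (excess 4.64). Lipg, a lipase, followed the opposite course, from 120.0 at 0 h to 1.80 at 30 h and 309 at 96 h. Total reads fell into 3 classes along this course. Of the 4290 genes 73.5% kept their direction within the 6, 12, 18, 30 and 36 h libraries, 91.7% within 0, 24 and 48 h and 61.6% between 72 and 96 h. Genes and directions came from a fit of these same libraries, so some agreement is built in. The shares therefore cannot decide whether depth class matters. The 30 h and 36 h libraries stood out of order on this course, with a naive minus formative score of 0.885 at 30 h and 1.22 at 36 h.

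The comparison of EpiLCs with and without Dox asks what Dox-induced ISY1 does on the way out of naive pluripotency. No line without the inducible ISY1 was given Dox, so effects of Dox itself and of ISY1 cannot be told apart. The gap in Isy1 narrowed with hour. Genes at least 2-fold different between single libraries meanwhile numbered 722 at 24 h and 2115 at 96 h. Naive pluripotency genes were among those higher with Dox at the matched hours: Tbx3 rose by 2.44 ± 0.30 on the log2 scale (SE, 4 pairs), Tcl1 by 2.42 ± 0.40, Esrrb (a nuclear receptor) by 1.80 ± 0.31 and Klf4 by 1.51 ± 0.17. Formative epiblast genes were among those lower, with Sfrp2 at −1.29 ± 0.25, Sall2 (a zinc finger factor) at −1.25 ± 0.17, Fgf5 at −1.18 ± 0.21 and Dnmt3b at −0.69 ± 0.10. The endoderm transcription factors Sox7 and Gata6 rose by 2.08 ± 0.34 and 2.03 ± 0.33, and Zscan4b and Zscan4c of the two-cell-like list by 2.04 ± 0.36 and 1.67 ± 0.27. The glycolytic enzymes Ldha (−0.98 ± 0.14) and Pfkl (−0.60 ± 0.11) fell, and Mdm2, which encodes the ligase that degrades p53, rose by 0.89 ± 0.14. Adjusted p values of the genes in these sentences lay between 0.0318 (Tbx3, Klf4) and 0.0477 (Sfrp2), and each changed the same way at 4 of 4 hours.

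In all 456 of 16117 genes passed (287 higher and 169 lower), of which 204 changed at least 2-fold (148 higher and 56 lower). These calls depend on few libraries: limma called 0 genes without the 48 h pair (3210 at an unadjusted p under 0.05) or without the 72 h pair (1924 unadjusted), 66 without the 96 h pair and 1122 without the 24 h pair. It also called 0 without hour as a block (1276 unadjusted) or without the intensity trend (3306 unadjusted), while edgeR called 522 on the 24 h and 48 h pairs alone, as run after the data were seen. The largest rises were in Pla2g7 (3.14 ± 0.60), the homeobox gene Nkx6-3 (2.86 ± 0.52), Pramel3 (2.84 ± 0.40) and Msln (mesothelin, 2.61 ± 0.51). The largest falls were in Cnn1 (calponin, −2.46 ± 0.27), the lipid transporter Mfsd2a (−2.19 ± 0.40), Phyhip (−2.13 ± 0.28) and Vash2 (a vasohibin, −1.98 ± 0.35). Among the 36 named genes that were called, the direction was the same under each alternative tried. Those of largest change were chosen for the same sign at every hour, so leaving out a pair could not turn them.

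Of the 21 naive genes 9 rose and 0 fell (15 and 0 adjusted over the list alone; list test adjusted p = 4.89e-08). Of the 15 formative genes 0 rose and 5 fell (0 and 9 adjusted over the list alone; 0.000723). In primitive and visceral endoderm 4 of 10 rose and 0 fell (6 and 0 adjusted over the list alone; 0.000311). The counts were 3 of 7 and 0 in the two-cell-like list (6 and 0; 2.65e-05). Among p53 targets they were 2 of 10 and 0 (5 and 0; 0.00169), the members being Mdm2 and Trp53inp1. In glycolysis 0 of 12 rose and 4 fell, Ldha, Pfkl, Pgam1 (−0.38 ± 0.07) and Pkm (−0.37 ± 0.07), with 1 and 7 adjusted over the list alone (0.00188). None of these 6 list calls held with an estimated correlation, where the first 5 had adjusted p = 0.487 with an estimated correlation and glycolysis adjusted p = 0.692 with an estimated correlation. All gene calls in this paragraph ended without the 48 h pair or the 72 h pair, where limma called 0 genes.

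Among the miR-290 and miR-302 targets, 0 of 13 were called with Dox and 6 were higher when adjusted over the list alone (median 0.27, list test adjusted p = 0.0966). Single members were called in core pluripotency (Lin28a, −0.56 ± 0.08, 0 higher and 1 lower of 9; 0 and 1 adjusted over the list alone) and let-7 targets (the same gene, 0 and 1 of 11; 1 and 2 adjusted over the list alone). They were also called in MEK/ERK targets (Spry2, 0.46 ± 0.08, 1 and 0 of 11; 4 and 1) and DNA methylation (Tet2, 1.40 ± 0.27, and Dnmt3b, 1 and 1 of 8; 3 and 2). The other lists had 0 called members in limma. Members higher and lower at an unadjusted p under 0.05 were then 3 and 1 of 10 in primitive streak, 1 and 1 of 8 in neuroectoderm, and 0 and 0 of 8 in mesoderm and heart. They were 2 and 0 of 5 in blood and endothelium, 2 and 1 of 9 in trophoblast, 5 and 1 of 9 in germline, 0 and 1 of 6 in feeder fibroblast and 2 and 1 of 7 in miR-17-92 targets. Last came 1 and 0 of 14 in the microRNA machinery, 1 and 1 of 10 in the Prp19 complex, 1 and 1 of 7 in Wnt targets, and 1 and 2 of 7 in the interferon response. Adjusted over the list alone, higher members remained in neuroectoderm (1, with 1 lower), trophoblast (1), germline (4, with 1 lower), miR-17-92 targets (2), microRNA machinery (1) and the Prp19 complex (1). The signs of mean, median and test differed in 7 lists, none below the threshold.

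The DGCR8 knockout asks how cells without this microRNA-processing factor pass through the same medium. Of the miR-290 and miR-302 targets, transcripts repressed by the main microRNA families of ESCs, 12 of 13 rose and 0 fell. The kinase Lats2 rose by 2.59 ± 0.25 (SE, 6 pairs), the Nodal antagonist Lefty1 by 2.33 ± 0.49, the caspase Casp2 by 2.10 ± 0.13 and the nuclear receptor Nr2f2 by 2.04 ± 0.41 (adjusted p = 0.00014, 0.00488, 2.91e-05 and 0.00413). Of the microRNA machinery list, whose test did not pass (adjusted p = 0.205), transcripts of the silencing factors Ago1 (1.58 ± 0.11), Tnrc6a (1.31 ± 0.12) and Tnrc6b (1.29 ± 0.10) rose. The naive genes Klf2 (3.64 ± 0.52), Prdm14 (2.74 ± 0.45), Nr5a2 (2.22 ± 0.42) and Tfcp2l1 (1.44 ± 0.20) rose, and Sox2 of the core list rose by 1.54 ± 0.36 while Lin28a fell by 1.92 ± 0.32. Of the formative list Pou3f1 was at −1.65 ± 0.49 (adjusted p = 0.024, lost without the 0 h pair), Wnt8a at −1.41 ± 0.37 and Sox3 at −1.20 ± 0.31. Fgf5 stood at −1.51 ± 0.54, and its call (adjusted p = 0.0478) ended when the 24, 48, 72 or 96 h pair was left out.

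In all 6899 of 16267 genes passed, 2941 higher and 3958 lower, and 2246 changed at least 2-fold (1063 and 1183). The split between directions depends on the scaling, with 3570 higher and 3121 lower under median-ratio scaling and 3561 and 3148 under a TMM-like scaling. Without hour as a block 3487 genes passed. The knockout is a different line from KH2-ISY1, so the line and the loss of DGCR8 cannot be told apart. The largest rises were in Nlrp12, a NOD-like receptor (4.49 ± 0.34), Smyd1, a muscle methyltransferase (4.41 ± 0.42), Samd9l (4.34 ± 0.35) and Lrrn2 (4.31 ± 0.28), followed by the interferon-induced GTPase Gbp4 (3.92 ± 0.25) and the muscle protein titin, Ttn (3.91 ± 0.27). The largest falls were in genes of the X-linked Xlr family, with Xlr3a at −4.94 ± 0.20, mean values of 3.78 in the knockout and 150.0 without Dox. Xlr5b, Xlr5a, Xlr5c and Xlr4a had knockout means under 0.4, so the size of their fitted folds depends on the pseudocount. Matn3, a matrix protein, fell by 4.71 ± 0.49.

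The list test called the miR-290 and miR-302 targets (12 higher and 1 lower adjusted over the list alone; median 1.41; adjusted p = 1.26e-06, and adjusted p = 0.0512 with an estimated correlation). It also called naive pluripotency, with 9 higher and 1 lower of 21 (10 and 1 adjusted over the list alone; adjusted p = 0.00681, and adjusted p = 0.81 with an estimated correlation). The lower naive gene, named after its value was seen, was Klf5. Members called in core pluripotency were 3 higher and 2 lower of 9, and in formative epiblast 3 and 5 of 15. In the microRNA machinery they were 5 and 2 of 14, Dgcr8 being among the lower. Of 7 miR-17-92 targets 4 rose and 0 fell (5 and 0 adjusted over the list alone; adjusted p = 0.0928), with Tgfbr2, a TGF-beta receptor, at 1.28 ± 0.17. Of 11 let-7 targets 4 rose and 2 fell (5 and 2 adjusted over the list alone), Lin28b up by 1.37 ± 0.30 and Mycn by 1.18 ± 0.15.

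Primitive streak genes split in the knockout, 4 higher and 3 lower of 11, with Wnt3 at −1.95 ± 0.39. In blood and endothelium 3 of 5 rose and 1 fell, with the blood factor Gata1 at 1.74 ± 0.41 and the endothelial receptor Tek at 1.74 ± 0.40. In mesoderm and heart 2 of 9 rose and 0 fell, the heart factor Tbx20 by 2.53 ± 0.53 and the receptor Kdr by 2.00 ± 0.36. Germline genes were lower in 4 of 9 and higher in 1 (2 and 4 adjusted over the list alone), with Taf7l at −2.16 ± 0.29 and Dazl at −1.58 ± 0.40. Glycolysis had 2 higher and 6 lower of 12, with Aldoa at −1.14 ± 0.16 and Ldha at −0.87 ± 0.16. MEK/ERK targets had 0 higher and 2 lower of 11 (Dusp4, −1.39 ± 0.18; Spry2, −1.33 ± 0.14), and DNA methylation 4 higher and 0 lower of 8 (4 and 1 adjusted over the list alone), with Tet2 at 1.14 ± 0.23 and Tet3 at 1.11 ± 0.14. Among Wnt targets Notum, a Wnt-inactivating enzyme, rose by 3.62 ± 0.39, with 1 higher and 2 lower of 8.

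Further knockout counts were 1 higher and 3 lower of 10 for primitive and visceral endoderm, 1 and 1 of 9 for neuroectoderm (Tubb3, 1.18 ± 0.24; Nes, −0.68 ± 0.13), 0 and 1 of 9 for trophoblast (Krt18, −1.52 ± 0.29), and 1 and 3 of 5 for feeder fibroblast (Thy1, −1.29 ± 0.29). They were 2 and 2 of 10 for the Prp19 complex (Ppie, −0.81 ± 0.12), 2 and 3 of 10 for p53 targets (Sesn2, 0.87 ± 0.12; 4 and 3 adjusted over the list alone), and 3 and 1 of 7 for the interferon response (Bst2, −1.74 ± 0.14). Of 7 two-cell-like genes 0 were called in limma (0 and 0 unadjusted). Where no count adjusted over the list alone is given for the knockout, it equalled the count over all genes. The signs of mean, median and test differed in 4 lists, none below the threshold.

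**Figure D2:**
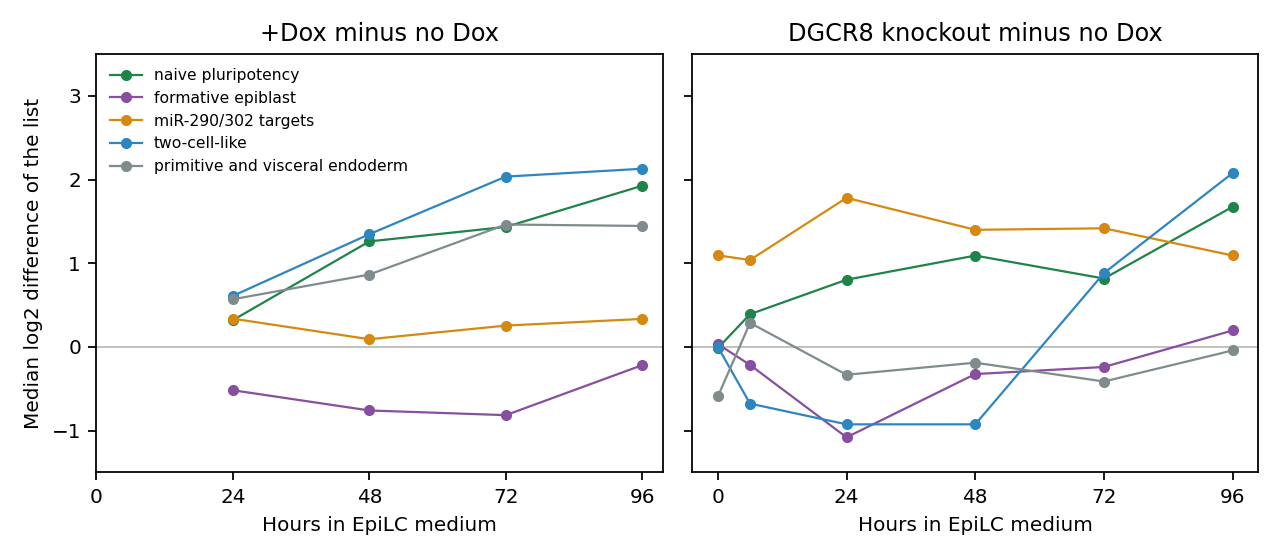
Median log2 difference of 5 gene lists at each hour, for Dox minus no Dox (left) and DGCR8 knockout minus no Dox (right), with 1 pair of libraries per point. The naive median goes from 0.32 at 24 h to 1.93 at 96 h with Dox, and the median of the miR-290 and miR-302 targets lies between 1.04 and 1.78 in the knockout and between 0.09 and 0.34 with Dox.

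The score of naive minus formative genes, a mean log2 difference, went from 5.48 at 0 h to −2.17 at 96 h without Dox. With Dox it was higher at 4 of 4 hours by a mean of 1.73 ± 0.60 (SD), with an exact permutation p of 0.13 (two-sided), the smallest that 4 pairs can give, so this design cannot pass 0.05. In the knockout it was higher at 6 of 6 hours by 1.12 ± 0.84 (SD), exact permutation p = 0.031 (two-sided, the smallest that 6 pairs can give; 0.0625 adjusted over these 2 tests). The knockout difference at 0 h was 8.98e-05, which is why p became 0.0625 with a pseudocount of 0.1 or 5. Single differences in the knockout were largest at 24 h (2.14) and 48 h (1.69).

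**Figure D3:**
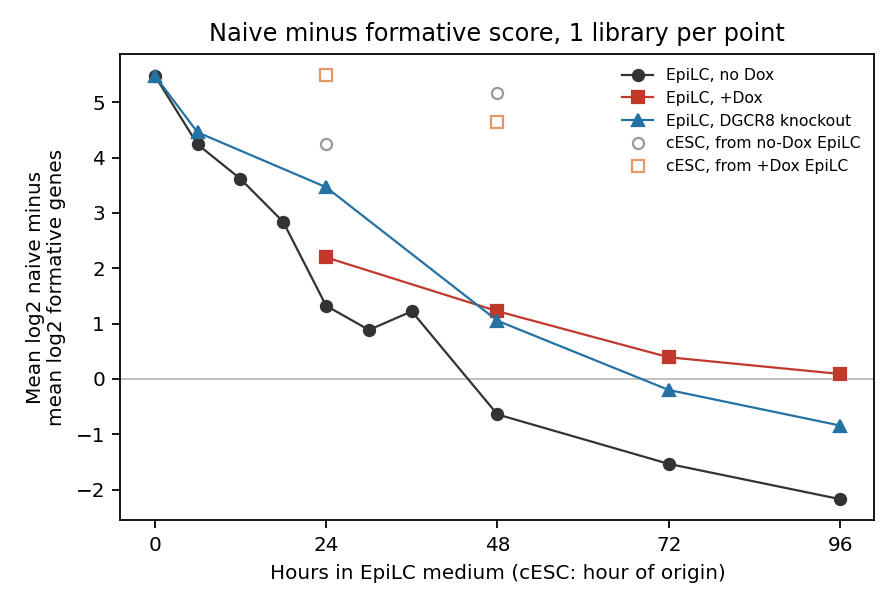
Mean log2 value of naive pluripotency genes minus that of formative epiblast genes (vertical) against hours in EpiLC medium, or the hour of origin for cESCs, with 1 library per point. Without Dox the score goes from 5.48 to −2.17, with Dox it is 0.0885 at 96 h, in the knockout −0.843, and the 4 cESC libraries lie between 4.24 and 5.49.

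Placed on the course without Dox by correlation across the 1000 most variable genes, which are not independent replicates, the libraries with Dox lay nearest to their own hour at 24, 48 and 72 h (r = 0.667, 0.632 and 0.678), and the 96 h library nearest to 72 h (r = 0.840). At 24 h the runner-up, 18 h, had the same r to 3 digits and took first place with 300 genes or with Spearman correlation. Knockout libraries at 24 h and 48 h lay nearest to 12 h (r = 0.461) and 30 h (r = 0.316), with 18 h for the first when 300 genes were used and 36 h for the second when 3000 were used. Those at 0, 6 and 72 h lay nearest to their own hour and that at 96 h to 72 h (r = 0.837). All 4 cESC libraries lay nearest to 0 h, with r between 0.499 for the 24 h origin without Dox and 0.871 for the 24 h origin with Dox.

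The cESC libraries ask whether EpiLCs of 24 h or 48 h, with and without Dox, return to the naive state when put back in 2i/LIF. In each cESC library the median of the naive list was above that of its EpiLC of origin and the median of the formative list below it, while members of both lists went either way. The naive median was 0.80 from 24 h without Dox (10 higher and 4 lower of 21) and 2.45 from 48 h without Dox (18 and 1). It was 1.14 from 24 h with Dox (11 and 2) and 1.43 from 48 h with Dox (12 and 2). The formative medians were −2.65, −2.98, −2.37 and −2.17. MEK/ERK targets had medians of −4.07, −3.37, −4.21 and −3.80. As single genes, Dusp6 went from 1254 in 24 h EpiLCs without Dox to 5.0 in their cESCs and from 1928 to 3.6 for 48 h with Dox, and Dppa3, a gene of naive cells and germ cells, from 9.10 to 654 for 24 h without Dox. Tfap2c, a trophoblast and germ cell factor, went from 1.80 to 197 for 48 h with Dox. Against 2i/LIF cells at 0 h the naive median remained lower, at −1.54, −0.48, −0.21 and −0.79 in the same order, and the two-cell-like median was 0.85, 0.88, 1.24 and 1.89.

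Counts of genes higher and lower against the EpiLC of origin were 1682 and 3470, 1213 and 2120, 849 and 1913, and 1130 and 1989, again in that order. Against 0 h they were 784 and 2851, 386 and 1570, 1439 lower of 1740 changed, and 655 and 1812. Of these the 24 h library without Dox depends most on scaling, with 2432 higher and 2652 lower than its EpiLC and 1253 and 2032 against 0 h under median-ratio scaling. Between cESCs from 24 h EpiLCs with and without Dox, 1908 genes were higher and 1079 lower with Dox (1367 and 1445 under median-ratio scaling), with the naive median at 0.91 and Tagln, an actin-binding protein, going from 217.5 to 3.5. From 48 h EpiLCs 649 were higher and 510 lower, with the naive median at −0.30, the two-cell-like median at 1.75 and the imprinted growth factor Igf2 going from 6.40 to 290.1. These are differences between single libraries and were not tested.

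The EB course asks which lineages appear as ESCs differentiate in suspension. Pluripotency genes fell, with log2 changes between the fitted ends of −6.12 for Dppa5a, −6.57 for Zfp42, −6.28 for Tdgf1 and −6.23 for Utf1 (adjusted p = 0.00057, 0.00478, 0.00136 and 0.00286). The neuronal gene Dcx went from a listed 0 at day 0 to 4109 at day 13, and the endoderm products Ttr (transthyretin) and Afp (alpha-fetoprotein) from a listed 0 to 1387 and 2807. The neural factor Pou3f2 rose by 9.52, the nephric and node factor Lhx1 by 8.47 and the heart factor Hand2 by 7.12. The vascular receptor Kdr rose by 4.96. In all 4505 of 16753 genes changed (2895 higher and 1610 lower), 4135 of them at least 2-fold. The count was 1919 without day 10, 2121 without day 13 and 2640 without day 2, and median-ratio scaling moved the median of all genes from 0.119 to −0.0101.

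The test called naive pluripotency (0 higher and 16 lower of 21; 0 and 19 adjusted over the list alone; adjusted p = 1.37e-08, and adjusted p = 0.436 with an estimated correlation) and primitive and visceral endoderm (12 and 0 of 16; 15 and 0; 1.68e-06). It also called neuroectoderm (11 and 0 of 13; 11 and 0; 5.19e-05) and core pluripotency (0 and 8 of 9; 0 and 8; 6.05e-05). Germline (0 and 4 of 10; 1 and 6; 0.00619) and MEK/ERK targets (1 and 4 of 11; 1 and 5; 0.0496) were called lower and mesoderm and heart (5 and 1 of 13; 6 and 1; 0.0496) higher. The last had adjusted p = 0.678 with an estimated correlation, and the 5 lists between had adjusted p = 0.632 with an estimated correlation, so no list call on this course held. Spry4, an inhibitor of receptor signalling, and Etv5 of the MEK/ERK targets fell by 6.62 and 3.20.

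Other counts on the EB course, higher and lower, were 7 and 2 of 15 for formative epiblast, 4 and 3 of 15 for primitive streak, and 3 and 2 of 8 for blood and endothelium. They were 6 and 0 of 9 for trophoblast, 5 and 0 of 11 for feeder fibroblast, 3 and 5 of 8 for the two-cell-like list, 5 and 2 of 13 for miR-290 and miR-302 targets (Nr2f2, 8.89; Lats2, 3.22). Next came 4 and 0 of 7 for miR-17-92 targets, 2 and 2 of 11 for let-7 targets (Trim71, −2.47) and 3 and 0 of 14 for the microRNA machinery (Ago1, 2.25). They were 0 and 1 of 10 for the Prp19 complex (Cdc5l, −1.74), 5 and 1 of 9 for Wnt targets and 0 and 1 of 10 for p53 targets. Last came 2 and 4 of 8 for DNA methylation (Tet1, −4.79), 5 and 0 of 8 for the interferon response (Usp18, 6.43) and 0 and 1 of 12 for glycolysis (Hk2, −2.03). Adjusted over the list alone, the pairs became 8 and 2 for formative epiblast, 3 and 3 for blood and endothelium, 6 and 1 for trophoblast and 9 and 0 for feeder fibroblast. They became 7 and 2 for miR-290 and miR-302 targets, 5 and 1 for miR-17-92 targets, 5 and 2 for let-7 targets, 6 and 2 for Wnt targets, 0 and 0 for p53 targets, 2 and 5 for DNA methylation and 6 and 0 for the interferon response, and stayed equal in the rest. The two-cell-like split rests on single days: without day 13 Zscan4c went from −0.84 to 1.80, Zscan4d from −1.01 to 0.98 and Tcstv1 from −0.93 to 0.58, and without day 0 Usp17la went from 0.79 to −1.20. Day 13 carries calls in several lists. The fibroblast collagen Col1a2 stood at 56.7 on day 10 and 2751 on day 13, the embryonic globin Hbb-y at 7.78 and 752 and the interferon-induced Isg15 at 7.78 and 130.0, and the call of each ended without day 13.

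In serum/LIF cells, where ISY1 was switched on without a change of medium, 168 genes were higher and 1164 lower with Dox. Beyond Isy1 the higher genes of largest difference were RP23-4F16.12, at 2435 with Dox and 63.6 without, and Mup6 and Gm28438 (log2 2.54 and 2.31). The lower ones included Adm (adrenomedullin), at 0.48 against 67.5, Stc1 (stanniocalcin), at 1.19 against 89.5, and H2-Ab1, an antigen-presenting protein (−4.17). The glycolysis median was −0.95 with 0 higher and 6 lower of 12, the two-cell-like median 0.63 (2 and 0 of 8) and the naive median 0.27 (1 and 0 of 21). Formative genes had a median of −0.38 (1 and 4 of 15), feeder fibroblast genes −0.48 (0 and 5 of 11), mesoderm and heart −0.74 (0 and 2 of 13) and miR-290 and miR-302 targets 0.02 (1 and 0 of 13). This is 1 library against 1, with no test.

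For microRNAs, the serum/LIF cells with and without Dox ask whether ISY1 changes microRNA levels. With Dox 26 of 113 microRNAs above the floor were higher and 3 lower in deposited values, with a median difference of 0.66, and 8 higher and 7 lower once libraries were scaled to equal medians. The miR-290 cluster, the main microRNA family of ESCs, had a median of 0.84 as deposited and 0.26 after median-ratio scaling, with miR-290 itself at 1.76, and its share of all values was 73.5% without Dox and 69.9% with it. The miR-17-92 cluster, which acts in growth control, had medians of 1.04 and 0.47, the Dlk1-Dio3 cluster of the imprinted locus 1.11 and 0.53, and let-7, the family that rises in differentiated cells, 0.85 and 0.30. Other medians as deposited and after scaling were −0.01 and −0.36 for miR-302-367, 0.71 and 0.13 for miR-200, 0.85 and 0.27 for miR-183 and 1.04 and 0.47 for the Sfmbt2 cluster. They changed sign with scaling for miR-106a-363 (0.41 and −0.16), miR-106b-25 (0.39 and −0.18), miR-15/16 (0.42 and −0.13), miR-130 and miR-301 (0.48 and −0.07) and the differentiation-associated list (0.22 and −0.35). The list of microRNAs made without DGCR8 had −0.73 and −1.30, but only 2 of its members were measured in KH2 cells. They were miR-320, at 1151.0 without Dox and 429.5 with it, and miR-344, at 27.3 and 26.4, under the floor.

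With siRNA against Isy1 in V6.5 cells the deposited values pointed the other way. Of 132 microRNAs 3 were higher and 65 lower in both libraries as deposited, whereas after median-ratio scaling 14 were higher and 5 lower of 114. The overall medians were −1.14 and −1.39 before scaling, and the direction of most differences therefore depends on the scaling. The 5 that were lower also after scaling were mir-26a-1, mir-9-1, let-7c-1, mir-433 and mir-543, with mir-26a-1 at −5.31 and −6.17 and mir-9-1 at −3.65 and −5.06 as deposited. These are entries for single loci, and others of the same microRNA went differently. The locus mir-9-2 was higher in both libraries after scaling (3.13 and 1.68) and mir-9-3 was at 2.38 in the second as deposited. How reads matching several loci were assigned is not stated. A fall of mir-26a-1, mir-9-1 or let-7c-1 therefore cannot be read as a fall of its microRNA, and sums over loci were not tested. The locus mir-26a-2, chosen after its values were seen, had 920.8 with the control siRNA and 1001.4 and 369.2 with siRNA against Isy1. Family medians as deposited in the first library, with the scaled value after each, were −0.79 and 0.28 for miR-290, −0.60 and 0.41 for miR-302-367, −1.29 and −0.26 for miR-17-92 and −1.81 and −0.76 for miR-106a-363. Next came −0.47 and 0.60 for miR-106b-25, −1.63 and −0.61 for let-7, −0.65 and 0.41 for miR-200 and −1.48 and −0.41 for miR-183. They were −1.68 and −0.65 for Dlk1-Dio3, −0.54 and 0.43 for Sfmbt2, −1.36 and −0.36 for the differentiation-associated list, −1.13 and −0.09 for miR-15/16, −1.51 and −0.54 for miR-130 and miR-301 and −0.16 and 0.90 for the DGCR8-independent list. The direction therefore flips with scaling for miR-290, miR-302-367, miR-106b-25, miR-200, Sfmbt2 and the DGCR8-independent list. In the second library miR-290 had −1.29 and, scaled, −0.00, and miR-17-92 had −1.45 and −0.19. The miR-17-92 medians in V6.5 cells cover 8 loci, against 6 microRNAs in KH2 cells, because all numbered loci of a name were counted. Loci outside the cluster may be among them, so these medians cannot be compared with those in KH2 cells. A limma fit of 2 libraries against 1 was made on deposited values only. It has 1 control library and carries the shift of whole libraries that scaling removes, so nothing is drawn from it.

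On the EB course the miR-302-367 cluster, an early epiblast family, had medians of −0.46 at day 1 and 4.80 at day 4 (6.37 scaled), with miR-302b going from 65.4 in serum/LIF to 1275 at day 4. The miR-17-92 cluster had 2.56 at day 1 (2.90 scaled) and 0.42 at day 4 (1.96 scaled), with miR-17 at 4.98 and miR-20a at 3.56 at day 1. The miR-290 cluster had 0.08 at day 1 (0.41 scaled) and −2.11 at day 4 (−0.57 scaled), and miR-292 went from 159455 to 3278 at day 4. In all 32 microRNAs were higher and 45 lower of 117 at day 1 (41 and 40 scaled), and 15 higher and 65 lower of 108 at day 4, where scaling turned the split to 53 higher and 38 lower. Day 4 medians whose sign scaling turned were −0.07 and 1.48 for miR-106b-25, −0.70 and 0.85 for miR-183, −0.49 and 0.93 for miR-15/16 and −0.23 and 1.24 for miR-130 and miR-301. The rest at day 4 were 2.01 and 3.56 for miR-106a-363, −1.65 and −0.47 for let-7, −1.94 and −0.41 for miR-200 and 0.10 and 1.60 for Dlk1-Dio3. They were −2.73 and −1.64 for Sfmbt2 and −2.23 and −0.86 for the differentiation-associated list. The DGCR8-independent list, here miR-320 and miR-344 only, had −3.27 and −1.77.

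On the EpiLC course 76 microRNAs were higher and 39 lower of 156 at 6 h against 0 h (42 and 46 scaled), and 75 and 39 of 158 at 48 h (41 and 49 scaled). The deposited heading of the 6 h values carries both 6 h and 0 h. It was read as 6 h, because 0 h has a heading of its own. The largest rise was miR-335 (4.36 and 4.30), followed by miR-543 (4.22) at 6 h and miR-450b (4.02) at 48 h, and the largest fall miR-5126 (−6.58 and −6.51) at 6 h and 48 h. Medians at 48 h as deposited and scaled were 2.40 and 1.67 for miR-302-367, 1.11 and 0.37 for miR-17-92, 2.64 and 1.90 for miR-106a-363, 1.12 and 0.39 for let-7 and −0.11 and −0.85 for miR-290. The share of miR-290 in all values was 74.8% at 0 h, 43.1% at 6 h and 40.9% at 48 h. Further medians at 48 h were 0.99 and 0.25 for miR-106b-25, 1.43 and 0.69 for miR-200, 2.11 and 1.37 for miR-183, and 1.14 and 0.44 for Dlk1-Dio3. The last were 0.76 and 0.08 for Sfmbt2, 1.43 and 0.69 for the differentiation-associated list, 1.25 and 0.59 for miR-15/16 and 1.80 and 1.07 for miR-130 and miR-301. The DGCR8-independent list, again miR-320 and miR-344 only, had −1.64 and −2.34. The 0 h library stood apart from all others of its table (highest r 0.776 across microRNAs, against 0.838 to 0.967 for each of the others). With 6 h in place of 0 h, as chosen after the data were seen, 6 were higher and 6 lower of 142 at 48 h, with miR-302a at 1.28, let-7a at −1.41 and let-7d at −1.70.

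**Figure D4:**
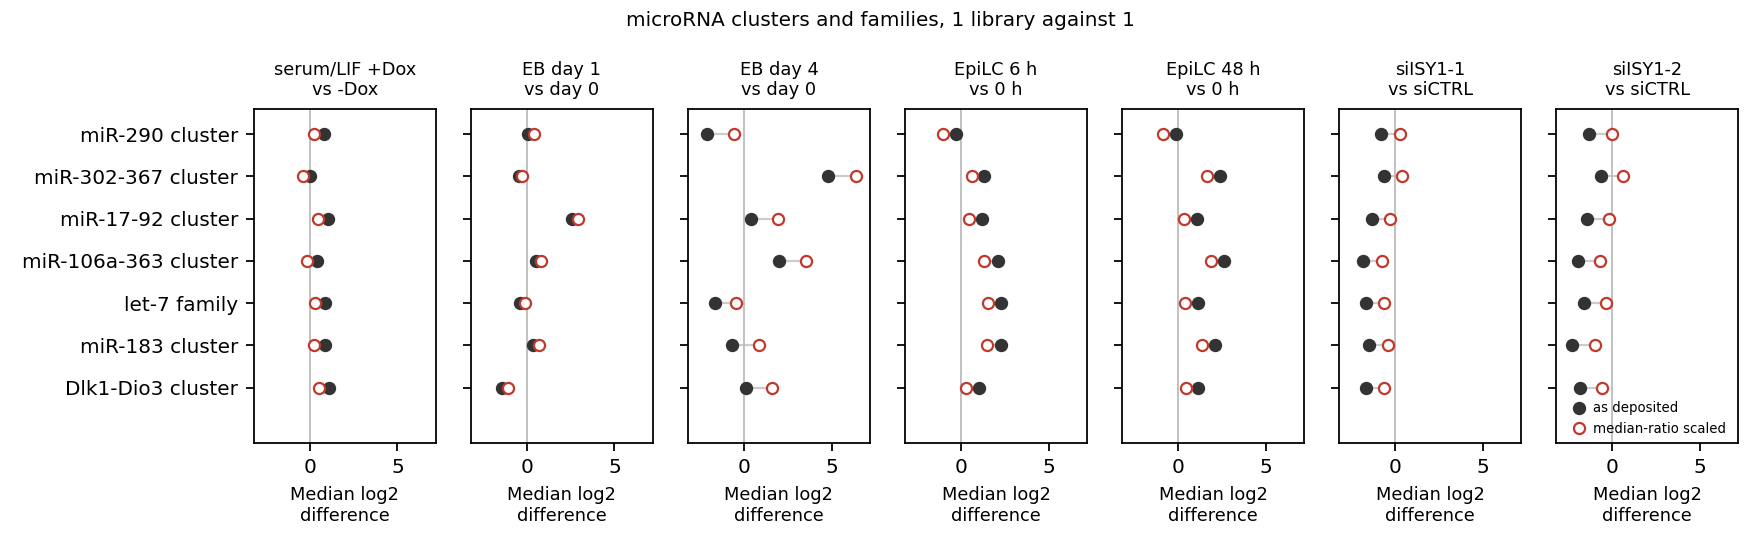
Median log2 difference (horizontal) of 7 microRNA clusters and families in 7 comparisons of 1 library against 1, as deposited (filled) and after median-ratio scaling (open). With siRNA the miR-17-92 list holds 8 loci, some of which may lie outside the cluster. At EB day 4 the miR-302-367 median is 4.80 and, scaled, 6.37, while in the first library with siRNA against Isy1 the miR-290 median goes from −0.79 to 0.28 and miR-302-367 from −0.60 to 0.41, so their direction flips with scaling.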

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

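Chosen only after the result was seen were the tests of library size for the 30 h and 36 h libraries, of paralogs and of depth for the Xlr genes, of a library-wide factor and of batches for the small RNA library, and both sets of other splits.

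The difference between EpiLCs with and without Dox was singled out because it changed with hour in 457 of 16117 genes by a limma interaction test (2752 at an unadjusted p under 0.05), rising in 278 and falling in 179. The genes named in this part were chosen after their values were seen. Nr0b1, a nuclear receptor of naive cells, had log2 0.08 at 24 h and 4.83 at 96 h (adjusted p = 0.00142), Dnmt3l −0.03 and 3.53 (0.00236), and Zfp42 0.28 and 2.68 (0.00236). Krt18, a keratin of trophoblast, went the other way, from 0.47 to −2.48.

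The knockout difference was singled out in the same way, with 85 of 16267 genes (2395 unadjusted), 61 rising and 24 falling. Msln went from −1.63 at 0 h to 3.87 at 96 h (adjusted p = 0.00255) and Tgfbi, an extracellular matrix protein, from −3.03 to 4.03 (0.00281). Axin2, a Wnt feedback gene, went from 1.48 to −2.97 (0.0162).

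Along the EpiLC course the 30 h and 36 h libraries stood out of order, the 36 h library lying nearer to earlier hours. Exchanging both labels changed the residual variance of the spline fit by −5.568%, whereas exchanging any other pair of neighbouring hours raised it by at least 7.403%. Library size is argued against, because total reads of both differed by 1.756%. For RNA of earlier cells in the 36 h library, the best mix of 0 h and 48 h values left an error of 1.711 (log2). The mean of 24 h and 30 h values left 0.670. Neighbouring hours can fit better whether or not earlier RNA is present, so this test cannot decide. An exchange of labels and RNA of earlier cells are candidate explanations that stay open, as does a culture that lagged at 36 h, which was not tested.

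Xlr genes lay near 0 in all knockout libraries. A loss of the whole stretch between the outermost Xlr genes is argued against, because only 11.9% of its other expressed genes (5 of 42) were at least 4-fold lower. These 5, named after their values were seen, were Gm14685, DXBay18, Gm5639, Gm18336 and Dusp9. A loss of a shorter part of the stretch was not tested. Reads shared between paralogs are argued against too, the summed Xlr values being lower in the knockout by at least 25.64-fold at every hour, and so is lower depth, the knockout library being the deeper one in 6 of 6 pairs. Smaller losses at the Xlr genes, a difference between lines and the absence of DGCR8 may each explain it, and the design confounds the last pair.

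The 2i/LIF small RNA library at 0 h stood apart from the 6 h and 48 h libraries. A library-wide factor is argued against, because the log2 differences between 6 h and 0 h had an SD of 2.446 over microRNAs, against 0.689 between 48 h and 6 h. A few dominant microRNAs are argued against, the highest correlation with another library being 0.7216 without the 10 most abundant. A difference between library batches cannot be told apart from the change of medium, since 0 h is the only 2i/LIF library of its table (highest correlation 0.7756), and either may lie behind the EpiLC microRNA differences.

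For the 456 genes with Dox, 3 of the 32 splits of the 8 libraries that could be fitted gave as many, the real one included. The other 2 part only the 72 h and 96 h pairs and, with hour as a block, hold 1 contrast, the difference with Dox in the late pairs itself (1271 genes each), so they say nothing about chance. Among the 8 splits that part every pair the highest other gave 0, and 8 splits are too few for a share under 0.05. For the 6899 genes in the knockout, 1 of 100 drawn splits, the real one, gave as many and the highest other gave 2220. Among the 32 splits that part every pair, only the real one gave as many and the highest other gave 0. A random grouping of these libraries is argued against as the source. The splits cannot separate the knockout from a difference between lines or cultures.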

How the results depend on the processing

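Chosen after the data were seen were the tests on the early or late pairs alone, those with edgeR, with 30 h and 36 h exchanged or left out, with depth class as a covariate and with 6 h in place of 0 h, and all others were chosen before the data were examined.

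Of 207 alternative values of the 37 answers to comparisons, 160 kept their direction and side of the threshold, or for counts stayed within 1.5 times. The EpiLC course count did so throughout, from 5887 to 8605. The others follow, and the cause was not tested except where said.

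The count with Dox was 233 with a pseudocount of 0.1, and limma called 0 genes without the intensity trend (3306 unadjusted) and 0 without hour as a block (1276 unadjusted). Leaving out a pair gave 0 (48 h or 72 h) to 1122 (24 h), and 66 without 96 h. The 72 h and 96 h pairs alone gave 3868, the 24 h and 48 h pairs 621, or 522 with edgeR. The knockout count was 3487 without hour as a block. The EB count ranged from 1919 (without day 10) to 5847 (without day 0), with 2121 without day 13 and 2640 without day 2.

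The knockout score difference was 1.112 and 1.027 with pseudocounts of 0.1 and 5, and 0.9151 to 1.343 with a pair left out. The exact two-sided p was 0.0625 each time, which with a pair left out is the smallest that 5 pairs can give. Staging moved to 18 h for the 24 h library with Dox (300 genes, and Spearman) and for the 24 h knockout library (300 genes), and to 36 h for the 48 h knockout library (3000 genes).

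Fewer genes pass a higher floor by construction. Genes changed in serum/LIF with Dox numbered 816 with a pseudocount of 5 and 796 with a floor of 20. For cESCs against 0 h a floor of 20 gave 1088 (48 h without Dox), 948 (24 h with Dox) and 1569 (48 h with Dox), and a pseudocount of 5 gave 1102 (24 h with Dox). Against the EpiLC of origin a floor of 20 gave 1781 (24 h with Dox). Between the 48 h cESCs a floor of 20 gave 559, and a pseudocount of 5 gave 633.

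MicroRNAs changed in serum/LIF with Dox numbered 52 with a floor of 20, 15 with a floor of 500 and 15 with median-ratio scaling. Floors of 20 and 500 gave 121 and 37 at EB day 1 and 142 and 36 at EB day 4. A floor of 500 gave 61 at EpiLC 6 h and 56 at 48 h, and 6 h in place of 0 h gave 12. With siRNA against Isy1, floors of 20 and 500 gave 114 and 29, median-ratio scaling 19, and limma 0 (131 unadjusted).

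Among named genes that were called, 5 on the EB course and 5 on the EpiLC course changed sign under some alternative, and none with Dox or in the knockout. In the last 2 fits the genes of largest change were chosen for the same sign at every hour. On the EB course Usp17la was −0.3407 with untransformed time and −1.205 (without day 0) to 1.308. With a day left out Lin28b was −0.2336 (without day 0) to 1.09, Tcstv1 −2.752 to 0.5789, Zscan4c −4.24 to 1.795 and Zscan4d −3.995 to 0.9834, the last 3 turning without day 13.

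On the EpiLC course Bax was 0.002187 with fewer degrees of freedom, 0.04284 with edgeR and −0.2607 to 0.08167 with an hour left out, turning without 0 h or 96 h (0.03935). Col1a1 was −0.5551, −0.5344 and −0.4949 (without 96 h) to 0.9812. Without 0 h Myc, Spry4 and Tek turned, with −0.3603 to 6.319, −2.947 to 5.629 and −1.97 to 0.294. Of the named genes that were called, all 36 with Dox lost their call under some alternative, 49 of 85 in the knockout, 46 of 86 on the EB course and 22 of 93 on the EpiLC course.

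DESeq2 was not run, since the values are normalised. A single read stands for 0.0952 to 0.935 normalised units, which limits what can be said of genes near 0.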

Other observations

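The tests of shared libraries and of a lag were chosen before their results were seen.

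The medians at single hours of the knockout that follow compare 1 library with 1, and none of these lists passed the test over all hours. The interferon response had a median of 2.21 at 0 h, with 5 higher and 1 lower of 7, and neuroectoderm a median of 2.16 at 96 h. The two-cell-like median went from −0.68 at 6 h to 2.08 at 96 h, with Zscan4c, chosen here after its values were seen, listed at 0 at 0, 6 and 24 h and at 123.6 at 96 h. With Dox, Zscan4c went from 2.8 at 24 h to 162.9 at 72 h and 132.6 at 96 h.

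On the EB course Zscan4c peaked at 378.8 on day 4, between 61.8 on day 2 and 51.8 on day 8.

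Genes at least 2-fold different between single libraries numbered 722, 1290, 1836 and 2115 at 24, 48, 72 and 96 h of Dox. In the knockout they numbered 3306, 2901, 3644, 3773, 2875 and 2603 in order of hour.

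Differences with Dox and in the knockout were weakly correlated across genes. Between different hours that share no library without Dox, the lowest correlation was 0.1226 and the highest 0.258. Shared libraries are therefore argued against as the whole source. Genes called in both fits, chosen here after their values were seen, went either way. Tet2 (1.40 with Dox and 1.14 in the knockout) and Lin28a (−0.56 and −1.92) kept their sign. Gata6 (2.03 and −1.68) and Sox7 (2.08 and −1.13) did not.

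A lag along the EpiLC course may account for part of the 48 h differences, since they ran against the later change without Dox (36 h to 72 h), with correlations across genes of −0.3444 for Dox and −0.2541 for the knockout.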
